A study of Chlorocebus sabaeus with 4 samples.

How the data were processed

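Total RNA of frozen corpus luteum from 2 vervet monkeys was amplified to biotin-labelled cRNA and hybridised, 1 array per sample, per the labels' protocols. The 4 arrays were those of the ad libitum animal, samples 1 and 2, and of the calorie restriction animal, samples 1 and 2, as the labels' diet and title give them. The deposited values are log2 signals per probe set. They were made with Affymetrix Power Tools and RMA (background correction, quantile normalisation and summary of probes), per the submitters' processing notes, and versions and settings are not given in the sources used here. Scanner files were not used here, so background and detection of single probes were not analysed. The number of arrays limits the precision of every value.

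The probe sets were designed on human genes, as the platform annotation shows, and a probe that mismatches the vervet sequence can lower a gene's signal. That loss is alike in all 4 samples unless the animals carry different alleles, so changes within an animal are less open to it than the difference between animals. Of 54675 probe sets, 62 were controls and were left out, 41097 had 1 gene symbol, 1801 had several and 11777 had none here; only those with 1 symbol were used. They named 19775 genes, of which 10523 had more than 1 probe set, and 15504 symbols (78.4%) matched a symbol or synonym in the RefSeq vervet annotation of assembly mChlSab1.0.hap1. No coordinates are given, since no build belongs to the arrays. Probe sets of near-identical relatives, such as HSD3B1 and HSD3B2, can share signal.

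A gene was represented by its probe set with the highest mean over the 4 samples. Genes under the median of that mean (log2 5.26) were left out of counts, fits and rankings, and list members were kept whatever their level. A change within an animal was sample 2 minus sample 1, with a threshold of 2-fold, and genes were counted as moving in both animals at 1.5-fold in each. These have no replicates and no test. Of the genes 2-fold apart with another probe set past the filter, the other probe set had the same direction in 312 of 330 (94.5%) in the ad libitum animal, 32 of 33 in the calorie restriction animal and 105 of 110 between animals.

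The common change, the opposed change and the difference between animals were tested with limma 3.58.1 (lmFit, eBayes with a trend on mean signal, Benjamini-Hochberg adjustment, adjusted p under 0.05) in R 4.3.3. The first 2 had the animal as a block and left 1 residual degree of freedom, and the third left 2. The residual of the common fit is the difference between the 2 animals' changes, and that of the opposed fit is the common change. For the difference between animals, p-values measure the spread between samples of these 2 animals and not the spread between animals. The procedure was tested on simulated data. For the difference between animals it called 0 of 67 genes with a planted log2 difference of 1, 39 of 67 with 2 and 56 of 66 with 3. It made 6 false calls. The simulated noise was independent between genes, with the same variance in every array, so these rates need not hold for the real arrays.

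The 26 gene lists and 16 cell type marker lists, the rule for named genes, the tests and the alternatives were fixed before the data were examined, except for list differences between animals without the ad libitum animal's sample 2, which were added after seeing the data, and for the tests of explanations. Those on endothelial against macrophage markers, oocyte markers, hybridisation controls, 3' to 5' differences and immediate early genes were chosen after their results had been seen, and that on hedgehog genes after 3 of its genes had been seen. A list's median change was placed among 10000 random lists of equal size drawn from 20 bins of mean signal, and counted as beyond them under the 2.5th or over the 97.5th percentile, as a description of these arrays. On simulated changes, drawn independently for each gene, 4.00% of 200 unaltered lists came out beyond, and a list of 15 genes shifted by 0.50 came out at percentile 99.7. Lists whose members move together were not simulated. The lists overlap in genes and are not independent.

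Named genes were the 12 with the largest increase and decrease in each animal past the level filter, and the 10 each way with the largest value of the smaller of the 2 changes for opposed and common changes. Where a member of a list is named for its size, it is among the largest changes of that list. For the difference between animals they were the 10 largest each way among genes whose samples did not overlap, since fewer than 10 passed the test. Symbols that are placeholders were passed over, and leading members of the lists and a fixed set of luteal and metabolic genes were added. Alternatives were 2 other level filters, cyclic loess and repeated quantile normalisation, the mean of all probe sets of a gene, leaving out probe sets of less specific design, other fold thresholds, no trend, sample number as a block, and leaving out each sample. RNA quality was read from the difference between 3' and 5' probe sets of GAPDH (1.29, 1.15, 1.31 and 1.41) and ACTB (1.61, 1.65, 1.48 and 1.73) in samples 1 and 2 of the ad libitum and then of the calorie restriction animal. Figures were drawn with matplotlib 3.10.9.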

Results

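RNA of the corpus luteum, the gland that forms from the ovulated follicle and makes progesterone, was profiled in 2 adult female vervet monkeys (Chlorocebus sabaeus) of 16 years. Monkey 1030 was fed ad libitum and monkey 1031 was placed on calorie restriction, and each animal gave 2 samples, numbered 1 and 2, so that it served as its own control for weight change. The labels do not say which number was collected first, and every change is given as sample 2 against sample 1. The 4 arrays carried 54675 probe sets designed on human genes, which gave values for 19775 genes, 9888 of them at or above a mean log2 signal of 5.26. Median log2 signal over all probe sets lay between 3.96 and 4.00. Each animal and sample number was represented by 1 array, so a change within an animal has no replicate check and no p-value. Genes are called higher or lower where they moved 2-fold or more, which is a rule of size and not a test. The ad libitum animal's sample 2 stood apart from the rest, with 912 to 1031 genes 2-fold from each other sample, whereas the other 3 differed from each other in 122 to 333.

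In the ad libitum animal, the question was how the luteal transcriptome differed between the animal's 2 samples. Sample 2 had far less RNA of the luteal steroid-making machinery. STAR, which carries cholesterol into mitochondria, was 11.2-fold lower (log2 change -3.49), the side-chain cleavage enzyme CYP11A1 was 4.56-fold lower (-2.19), and HSD3B2, of the enzyme pair that makes progesterone, was 15.0-fold lower (-3.91). Aromatase, CYP19A1, was 62.4-fold lower (-5.96), the HDL receptor SCARB1 was 12.8-fold lower (-3.68), and the luteinising hormone receptor LHCGR was 4.29-fold lower (-2.10). Among 11 measured markers of luteal steroidogenic cells, 9 were lower and none higher, with a median of -3.49 that lay below all 10000 random gene lists matched on signal.

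In all, 264 genes were higher and 651 lower in sample 2 of this animal. The largest decreases past the level filter were in NOG, a secreted BMP antagonist (-6.44, with sample 2 at 1.88, under the 25th percentile of all genes, so its size and rank are unsure), CYP19A1, the glycerol channel AQP9 (-5.41), the inhibin alpha subunit INHA (-5.32), MRAP, an accessory protein of melanocortin receptors (-4.75), and the interleukin-1 receptor antagonist IL1RN (-4.58). CCDC134 (-4.48), the phosphatase DUSP5 (-4.42), CPO (-4.38, sample 2 also under that percentile), the lysophospholipase ENPP2 (-4.37), TNFRSF11B, or osteoprotegerin (-4.36), and MXRA5 (-4.25) followed. The largest increases were in ZAR1 (3.70) and ZP4 (3.64), both oocyte genes, and in the macrophage chitinase CHIT1 (3.58), MLANA (3.30) and IHH, a hedgehog ligand (2.78). BHLHE41 (2.71), the theca cell hormone INSL3 (2.66), ELAVL2 (2.63), MYRIP (2.51), CHRDL1 (2.51), the lysosomal protease CTSK (2.47) and the sterol hydroxylase CYP27A1 (2.38) completed the 12. With the mean of all probe sets of a gene in place of the brightest, 10 of these 24 changes differed by more than 0.50 on the log2 scale or came under 2-fold, all in an unaltered direction. CYP19A1 came to -1.43, SCARB1, named above, to -1.81, IL1RN to -1.74, CCDC134 to -2.56 and BHLHE41 to 1.10. The other probe set of CCDC134 past the filter gave -0.63.

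Blood vessel genes had lower medians in the same comparison. Of 24 angiogenesis genes, 8 were lower and none higher (median -0.43), among them VEGFA (-3.17), the main vascular growth factor, VEGFC (-1.88), the apelin receptor APLNR (-2.44) and the VEGF receptors KDR (-1.80) and FLT1 (-1.63). Endothelial markers had a median of -0.84, with 6 of 15 lower, including CDH5 (-1.78) and PECAM1 (-1.42). Both medians lay below the range of random lists. So did those of the unfolded protein response (6 of 20 lower, 1 higher, median -0.63; HSPA5 -1.32, CALR -1.11), extracellular matrix (6 of 27 lower, 2 higher, median -0.39; COL4A1 -1.90, THBS2 1.33), interferon-stimulated genes (3 of 26 lower, median -0.25; ISG20 -1.79, IFI27 -1.39), cell cycle (5 of 32 lower, median -0.21; MKI67 -1.44, RRM2 -1.30) and glycolysis and hypoxia (4 of 25 lower, 1 higher, median -0.54; ADM -3.22, HK2 -2.66).

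Lipid genes were lower in part. Of 18 steroid synthesis genes, 7 were lower and 1, CYP17A1 (1.19), was higher (median -0.63). The prostaglandin list had 4 of 18 lower (median -0.33), led by the luteolytic receptor gene PTGFR (-3.78, below the level filter). Cholesterol synthesis and uptake had 4 of 19 lower (median -0.27), and fatty acid oxidation 2 of 18 lower (median -0.27). In these lists no other gene was higher. The cholesterol list came within the random range with the mean of all probe sets (-0.12), fatty acid oxidation after cyclic loess (-0.20), and the prostaglandin list with only members past the level filter (-0.33). Fatty acid synthesis and storage stayed within the random range (median 0.05), with 4 of 21 lower and 3 higher, DGAT1 at -2.87 and CD36 at 1.19. Of the adipokine genes, 3 of 14 were lower, NAMPT (-2.10), APLNR and the adiponectin receptor ADIPOR2 (-1.41), while ADIPOR1 (-0.63) and LEPR (-0.02, below the level filter) were not 2-fold apart. Nor were the insulin receptor INSR (-0.02), the cholesterol exporter ABCA1 (0.04), cyclooxygenase-2, PTGS2 (-0.17), or HSD3B1 (-0.20). PTGS2 and HSD3B1 lay below the level filter, and whether the probes for HSD3B2 also read its close relative HSD3B1 was not analysed here.

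Markers of several other cell types had higher medians in sample 2. Oocyte markers had a median of 0.58, with 2 of 11 higher, ZP4 and FIGLA (1.85, below the level filter). Most oocyte markers lay below that filter, and too few passed it for a median of those alone. Macrophage markers had a median of 0.40, with AIF1 (1.23) and FCER1G (1.05) higher and CD163 (-1.28) lower among 14. The MHC class II list, of antigen-presenting cells, had a median of 0.46, with 1 of 10 higher. Theca and interstitial markers had a median of 0.37, with 3 of 7 higher, INSL3, CYP17A1 and TCF21 (1.06), and 1 lower, STAR, which the luteal list also holds. Smooth muscle and pericyte markers had a median of 0.36, with 3 of 14 higher and 2 lower. These medians lay above the range of random lists, although with the mean of all probe sets that of the theca list was 0.17, within it. Markers of T and NK cells (median 0.11), B and plasma cells (0.14), neutrophils (-0.036), mast cells (-0.20) and surface epithelium (-0.089) lay within the random range. Granulosa markers (median 0.43, mean -0.82) and the hormone receptor and inhibin list (median 0.39, mean -0.35) had medians above the random range and means of opposite sign. INHA and INHBA (-3.42) were lower and FST (2.29) and INHBB (1.21) higher in both, and CYP19A1 (-5.96) and NR5A2 (-3.07) were lower in the granulosa list. The receptor median was -0.044 with the mean of all probe sets and the granulosa median -0.32 with only members past the level filter, both within the random range.

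**Figure D1:**
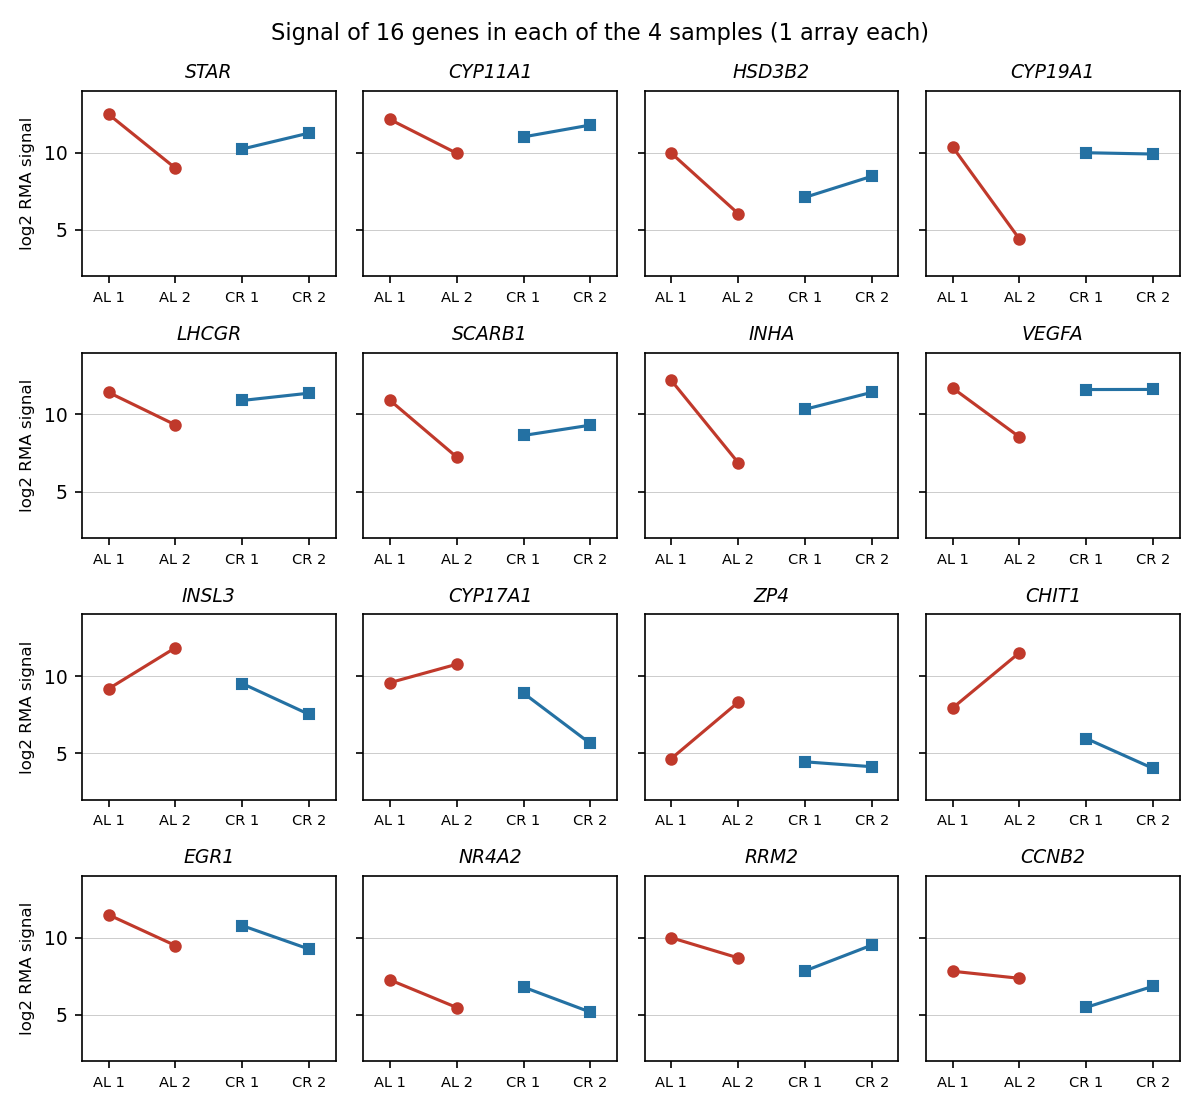
Log2 RMA signal of 16 genes in the 4 samples, 1 point per array, with circles for the ad libitum animal (AL) and squares for the calorie restriction animal (CR); lines join sample 1 to sample 2 of an animal. HSD3B2 went from 9.97 to 6.06 in the ad libitum animal and from 7.11 to 8.47 in the calorie restriction animal.

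In the calorie restriction animal, the same question gave smaller changes, with 49 genes higher and 73 lower in sample 2. Cell cycle genes were among the increases. RRM2, a subunit of ribonucleotide reductase, was 3.18-fold higher (1.67), UBE2C was 2.74-fold higher (1.46), PRC1 was 2.67-fold higher (1.42) and the mitotic cyclin CCNB2 was 2.58-fold higher (1.36). Of 32 cell cycle genes, 9 were higher and none lower, and their median of 0.63 lay above all random lists.

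The largest increases past the level filter were in SBSPON (1.89), the antimicrobial peptide DEFB1 (1.86), PCLAF, a partner of PCNA (1.80), CPO (1.75), RRM2, GAP43 (1.60), DLGAP5 (1.53), ANLN (1.53), the bicarbonate transporter SLC4A4 (1.53), UBE2C, SLC25A15 (1.43) and KYNU (1.42). PCLAF, DLGAP5 and ANLN also act in dividing cells. The largest decrease was in CYP17A1, the enzyme of androgen synthesis, at 9.57-fold (-3.26). ANPEP (-2.38), the Notch target HES1 (-2.27), INSL3 (3.99-fold), CHIT1 (-1.94), FOS (-1.92), galanin, GAL (-1.80, sample 2 under the 25th percentile of all genes), TENM4 (-1.74), NEFH (-1.73), CHRDL1 (-1.67), KLF10 (-1.65) and NR4A2 (-1.62) followed. With the mean of all probe sets, 11 of the 24 differed by the same measure, all in an unaltered direction. CYP17A1 came to -1.66, GAP43 to 0.72, SLC4A4 to 0.54 and ANPEP to -0.65. Of the genes that act in dividing cells, RRM2 came to 1.10 and PCLAF to 1.04.

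Markers of luteal steroidogenic cells had a higher median here. Of 11, 4 were higher and none lower (median 0.67), namely HSD3B2 (1.36), the cortisol-activating enzyme HSD11B1 (2.38-fold), INHA (1.10) and STAR (1.03), while CYP11A1 (0.77), SCARB1 (0.67), LHCGR (0.47) and CYP19A1 (-0.08) were under 2-fold. The steroid synthesis list had 3 of 18 higher and 1 lower (median 0.18). The oxidative phosphorylation genes shifted slightly and as a group, with a median of 0.27 above all random lists, though none of 29 reached 2-fold. Smooth muscle and pericyte markers (median 0.22) had 3 of 14 higher, SYNPO2 (1.27), ACTG2 (1.16) and TAGLN (1.11). Red blood cell markers (median 0.31, none of 8 at 2-fold, most of them below the level filter) also lay above the random range. The hormone receptor and inhibin list (median 0.17, 1 of 13 higher, INHA) lay just above it, and within it after cyclic loess (0.16), with the mean of all probe sets (0.063) and with only members past the level filter (0.090).

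Several regulatory lists lay lower. Clock and glucocorticoid genes had a median of -0.42, with BHLHE40 (-1.47) and BHLHE41 (-1.22) lower among 18. The insulin and IGF list had a median of -0.23, with IGFBP1 (-1.03, below the level filter) and IGFBP3 (-1.05) lower among 20, whereas INSR (-0.24) was not 2-fold apart. Angiogenesis (median -0.22, 1 of 24 lower), endothelial markers (-0.21, none of 15 at 2-fold), matrix proteases (-0.18, 1 of 24 lower, MMP9 at -1.51) and cytokines (-0.23, 3 of 25 lower) also lay below the random range. With the mean of all probe sets the angiogenesis (-0.076) and matrix protease (-0.091) medians came within that range. In the cytokine list CCL2, a monocyte attractant below the level filter, was the only gene higher (1.82). Of the 42 lists, 23 lay beyond the central 95% of random lists in the ad libitum animal and 14 in the calorie restriction animal. If genes changed independently, 2.1 would by chance. Members of such lists can move together, so the excess over 2.1 is not a test.

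**Figure D2:**
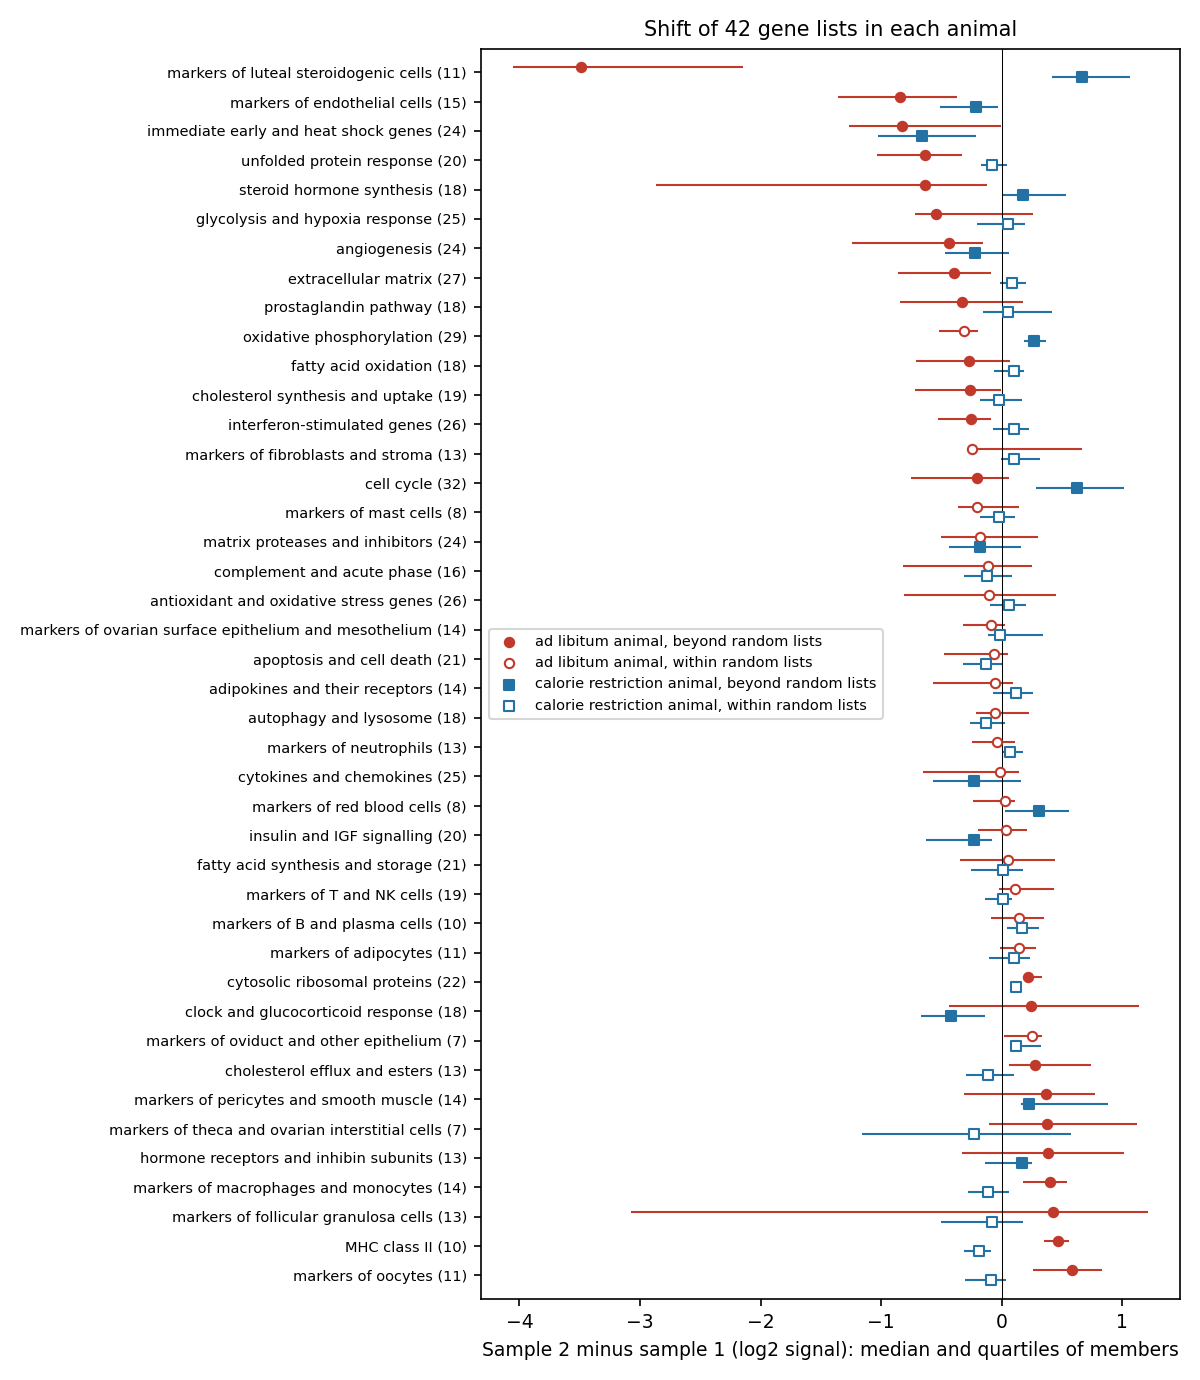
Median log2 change (sample 2 minus sample 1) of 42 gene lists in each animal, with bars from the first to the third quartile of the members and the number of measured members in parentheses; filled symbols lie beyond the central 95% of random lists matched on signal. Markers of luteal steroidogenic cells sit at -3.49 in the ad libitum animal and at 0.67 in the calorie restriction animal.

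Because the series title names weight gain and weight loss, genes that moved in opposite directions in the 2 animals were counted. These directions follow the sample numbers, whose order of collection is not given. If the order were reversed in either animal alone, the opposed and the common changes would change places. Of 9888 genes, 143 were at least 1.5-fold higher in the ad libitum animal's sample 2 and 1.5-fold lower in that of the calorie restriction animal, and 117 went the other way, where independent lists of these sizes would share 37.1 and 30.3. The first group was led by INSL3, CHIT1, CHRDL1, GSTM3 (2.00 and -1.53), the gelatinase MMP9 (1.80 and -1.51), the chemokine CXCL12 (1.46 and -1.44), TMEM35A (1.44 and -1.62), DDIT4L (1.36 and -1.33), COL4A4 (2.00 and -1.30) and BEND5 (1.39 and -1.28). The opposite group was led by SBSPON (-2.21 and 1.89), DEFB1 (-2.46 and 1.86), CPO (-4.38 and 1.75), GAP43 (-3.43 and 1.60, with the ad libitum sample 2 under the 25th percentile of all genes), ANLN (-2.16 and 1.53), SLC25A15 (-2.53 and 1.43), KYNU (-1.92 and 1.42), the phospholipase PLA2G5 (4.01-fold lower and 2.67-fold higher), the retinoic acid binding protein CRABP2 (-1.86 and 1.41) and HSD3B2 (-3.91 and 1.36). With the mean of all probe sets GSTM3 came to 0.94 and -0.77, COL4A4 to 0.72 and -0.46, and BEND5 to 0.67 and -0.48.

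Luteal markers and some theca markers had opposite pairs of signs. Of the 11 luteal markers, 9 had a negative change in the ad libitum animal and a positive one in the calorie restriction animal, and none had the opposite pair. Of 7 theca and interstitial markers, 4 had the opposite pair, among them CYP17A1 (1.19 and -3.26) and INSL3 (6.31-fold higher and 3.99-fold lower), and 2 had the pair of the luteal markers. The theca list's median for the opposed change (0.18) lay within the random range. Of 29 oxidative phosphorylation genes, 26 had a negative change in the ad libitum animal and a positive one in the other, although none reached 2-fold and the list's median in the ad libitum animal (-0.31) lay within the random range. The same pair of signs was found in 21 of 32 cell cycle genes. The bacterial control RNAs that are added to follow hybridisation divided the arrays in the same pattern: their mean log2 signal was 10.58 and 9.85 in samples 1 and 2 of the ad libitum animal and 10.09 and 10.54 in those of the calorie restriction animal. Across the 9888 genes, which are not independent replicates, the 2 changes had a Pearson r of -0.27 and a Spearman rho of -0.24.

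**Figure D3:**
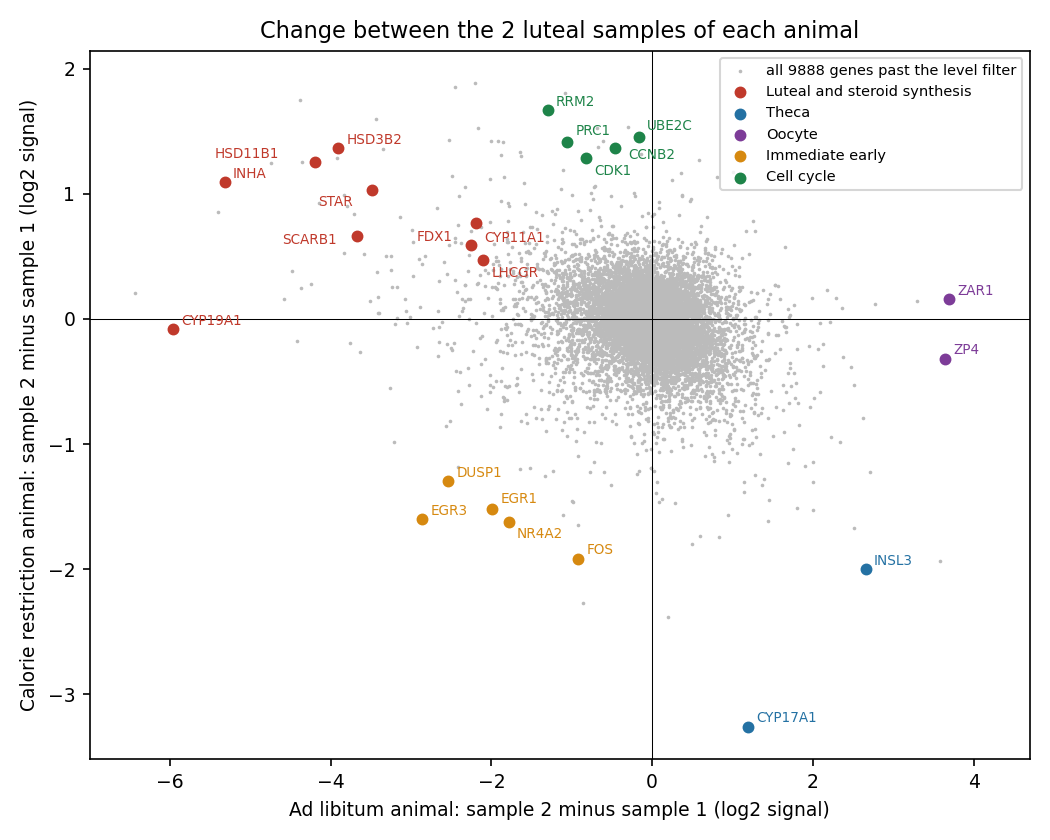
Change in the ad libitum animal (horizontal axis) against change in the calorie restriction animal (vertical axis), both as log2 signal of sample 2 minus sample 1, for 9888 genes in grey, with named luteal, theca, oocyte, immediate early and cell cycle genes in colour. STAR lies at -3.49 and 1.03, CYP17A1 at 1.19 and -3.26, and NR4A2 at -1.79 and -1.62.

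Genes that moved alike in both animals were mostly lower in sample 2. At 1.5-fold in both, 74 were lower and 12 higher, where independent lists would share 59.2 and 19.0. Immediate early genes, which respond within minutes to stimulation, were listed together with heat shock genes. The median of that list was -0.83 in the ad libitum and -0.66 in the calorie restriction animal, each below all random lists, and 16 of 24 had a negative change in both, 11 of them by 1.5-fold or more. NR4A2 (-1.79 and -1.62), EGR3 (-2.87 and -1.60), EGR1 (-1.99 and -1.52) and the phosphatase DUSP1 (-2.54 and -1.29) were 2-fold lower in both.

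The list of 10 was completed by MALAT1 (-1.33 and -1.26), IL15 (-1.23 and -1.21), RHOB (-1.65 and -1.20), CXCL10 (-1.53 and -1.19), the retinoic acid synthesis enzyme ALDH1A2 (-2.42 and -1.19) and TOB1 (-1.11 and -1.57). The genes with the largest joint increase were BACH2 (1.00 and 1.17), NRXN3 (0.81 and 1.13), TPD52L1 (1.26 and 0.78), CSTA (1.28 and 0.70), PCDH7 (1.17 and 0.70), ANKRD35 (0.69 and 0.82), MT1H (0.68 and 0.64), SSBP3-AS1 (0.67 and 0.62), SHISA4 (0.61 and 0.74) and TPM2 (0.59 and 0.69). Probe sets disagreed for MALAT1, whose other probe set past the filter gave 0.74 and -0.08, and for PCDH7, whose other probe set gave -0.29 in the ad libitum animal. With the mean of all probe sets RHOB came to -0.51 and -0.28 and DUSP1 to -1.09 and -0.47. MALAT1 came to -0.17 and -0.39, ALDH1A2 to -1.11 and -0.62, and IL15 to -0.85 in the ad libitum animal. Among the increases BACH2 came to 0.70 and 0.56.

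When both animals were fitted together with limma and the animal as a block, 0 genes passed a Benjamini-Hochberg adjusted p of 0.05 for a common change, and 0 for an opposed change. At an unadjusted p of 0.05, 180 and 738 genes passed, where 494.4 would by chance, and without a trend on signal the counts were 160 and 738. The low count and the high count are not separate evidence, since the residual of each fit is the other change. In simulated data with the same 9888 genes, the fit for the common contrast called 1 of 67 genes with a planted log2 change of 1. It called 7 of 67 with a change of 2 and 54 of 66 with a change of 3. For the opposed contrast it called 2 of 67, 59 of 67 and 65 of 66. False calls numbered 6 for the common and 9 for the opposed contrast. The simulated noise was independent between genes and had the same variance in every array. In the real data the ad libitum animal's sample 2 stood apart, so these rates need not hold there.

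Averaged over their 2 samples, the animals differed in the medians of endothelial, angiogenesis, interferon and cell cycle lists. The median of smooth muscle and pericyte markers was lower in the calorie restriction animal (-0.75), opposite to that of endothelial markers. Endothelial markers had a median difference of 0.74 (calorie restriction minus ad libitum animal), with 4 of 15 genes 2-fold higher in the calorie restriction animal, among them TIE1 (1.59). Angiogenesis genes had a median of 0.58, with 7 of 24 at 2-fold, such as FLT1 (1.69). Interferon-stimulated genes had a median of 0.50, and in 17 of 26 both samples of the calorie restriction animal lay above both of the other, led by IFI44 (1.61). Cell cycle genes lay lower in the calorie restriction animal, with a median of -0.76 and 10 of 32 at 2-fold, including TTK (-1.74). All of these medians lay outside the random range, as 16 of 42 did in this comparison. Without the ad libitum animal's sample 2, which stood apart from the other arrays, the endothelial median was 0.28 with 1 gene at 2-fold, the angiogenesis median 0.14 with 1, the interferon median 0.27 with 1, and the cell cycle median -1.03 with 17. TIE1 then came to 1.05 and FLT1 to 0.87, and VEGFA went from 1.49 to -0.094. Of the 16 lists, 12 then stayed beyond the random range on the same side and 4 did not, and luteal cell markers went from 0.12 to -0.74.

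Single genes did not pass the test. With 2 samples per animal and 1 animal per diet, limma called 0 of 9888 genes at an adjusted p of 0.05, and 522 at an unadjusted p of 0.05 with the trend on signal or 530 without. In 3493 genes (35.3%) the samples of the animals did not overlap, where chance gives 33.3%, and the largest differences among these were named. EGFL6 (4.00, SE 0.83), the peptide-processing enzyme CPE (3.95, SE 0.69), CTHRC1 (3.38, SE 1.18), the EGF receptor ligand TGFA (3.31, SE 0.74, its ad libitum sample 2 under the 25th percentile), the muscarinic receptor CHRM3 (3.21, SE 0.76), MRO (3.17), PI16 (2.95), granulysin, GNLY (2.91), CHAD (2.88) and PTGR1 (2.83) were higher in the calorie restriction animal.

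Higher in the ad libitum animal were CHIT1 (-4.74, SE 1.32), the Wnt inhibitor WIF1 (-4.32, SE 0.37, its calorie restriction sample 1 under the 25th percentile), the carboxylesterase CES1 (-3.74, SE 0.38), complement C3 (-3.55, SE 0.66), MFAP4 (-3.22), BHLHE41 (-3.17), CYP17A1 (-2.91), BOC (-2.81), follistatin, FST (-2.73) and MLANA (-2.68). The smallest adjusted p from limma, 0.442, was shared by CHAD, WIF1, CES1, RELN and PDE8B. Another probe set of BOC gave -0.0013, and with the mean of all probe sets 9 of the 20 named differences came out otherwise in size, all in an unaltered direction, such as TGFA at 1.27 and CHRM3 at 1.45. Without the ad libitum animal's sample 2, MRO came to 1.09, CTHRC1 to 1.56, CHRM3 to 2.06, CHIT1 to -2.95, BHLHE41 to -1.82, MLANA to -1.03 and FST to -1.59, and C3 (-4.51) was then the largest of the 20. Without that animal's sample 1, MRO was 5.24, CTHRC1 5.19 and MLANA -4.33, and CYP17A1 was -4.54 without sample 1 and -1.28 without sample 2 of the calorie restriction animal. Without the ad libitum animal's sample 1 the limma fit called 474 genes, 325 higher and 149 lower in the calorie restriction animal, against 0 without any of the other 3 samples. Animal and diet cannot be told apart, since each diet was given to 1 animal.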

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

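The tests of explanations in this part were chosen after the results they bear on had been seen; the counts, lists and alternatives had been planned. Several results pointed in opposite directions in the 2 animals, and each rests on 1 sample pair per animal and on sample numbers whose order is not given. They were the 143 genes higher in the ad libitum and lower in the calorie restriction animal, the 117 with the opposite pair, and 4 gene lists beyond random lists on opposite sides. In the limma fit of the opposed change 0 of 9888 genes passed an adjusted p of 0.05 (smallest 0.524), and 738 passed an unadjusted p of 0.05. Luteal cell markers had medians of -3.49 in the ad libitum and 0.67 in the calorie restriction animal, steroid synthesis genes -0.63 and 0.18, cell cycle genes -0.21 and 0.63, and clock and glucocorticoid genes 0.25 and -0.42. In the ad libitum animal the clock median came within random lists with the mean of all probe sets (0.14) and with only members past the level filter (0.097). The opposed change was taken as the mean of the ad libitum change and the other animal's change with its sign turned. For it, the medians of these lists were -2.17, -0.33, -0.38 and 0.40, each beyond random lists. Because the lists were picked for medians on opposite sides, these values add no separate evidence. They describe these arrays and are not a test across animals.

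The first pattern weighed is the loss of luteal cell genes in the ad libitum animal's sample 2, where all 11 luteal markers had their lowest value of the 4 samples. A smaller share of luteal cells with every other cell type in proportion would raise the markers of those types alike. Endothelial markers (quartiles -1.36 and -0.37) lay below macrophage markers (quartiles 0.17 and 0.54), with a difference of medians of -1.24, so these 2 lists did not rise alike. They were picked after their medians had been seen, so the difference cannot serve as a test. A smaller luteal share in which other cell types shift unequally stays open. For the control transcripts GAPDH and ACTB, RNA degradation was argued against by a mean 3' minus 5' difference that lay under the highest of the other samples (-0.17). Luteal genes were not read in this way. Oocyte markers were highest in that sample in 7 of 11, with ZP4 at 8.30 against 4.13 to 4.65 elsewhere, but oocyte genes prompted this count. Most of the 11 also lay below the level filter. In the ranking set beforehand, ZAR1 (8.12 against 4.42 to 4.68 elsewhere) and ZP4 were the largest increases, on the array that holds the luteal loss. Oocyte-bearing tissue in that sample stays open, and whether it accounts for the luteal loss was not tested. Feeding, body weight and the age or regression of the corpus luteum stay open and untested, with 1 animal and 1 sample of each number.

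The opposed changes coincide with the split of the hybridisation controls, which changed by -0.72 (SD 0.15, 18 probe sets) in the ad libitum and 0.45 (SD 0.16) in the calorie restriction animal. In the ad libitum animal the luteal markers' median minus the mean of the controls was -2.76, more than 2 SD of the controls. In the calorie restriction animal it was 0.215, under 2 SD of the controls. The arrays were quantile normalised, and the median change over genes past the level filter was -0.013 and -0.026 in the 2 animals. A shift of the controls therefore need not carry over to other genes by the same amount. The subtraction cannot decide on a hybridisation effect in either animal, and such an effect stays open. Diet and weight change remain open and untested.

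Immediate early and heat shock genes had the same direction by sample number in both animals, with the higher of the 2 medians at -0.66. The mean 3' minus 5' difference of GAPDH and ACTB changed by at most 0.18 in either animal, which argues against degradation of these control transcripts. Immediate early genes were not read in this way. Because the pattern was picked for its shared direction, that direction says nothing on weight change, which stays open. Handling of the tissue, time of collection and stage of the cycle could each act on such genes; none is given in the sources used here, and none was tested.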

How the results depend on the processing

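The list differences without the ad libitum animal's sample 2 were chosen after seeing the data. Counts moved with the fold threshold and with the stricter level filter, which by construction change how many genes can pass, and with the mean of all probe sets. The values below follow one order: ad libitum higher and lower, calorie restriction higher and lower, opposed (ad libitum higher, then lower), and both higher and both lower. With thresholds of 1.5-fold in 1 animal and 0.32 on the log2 scale in both they were 943, 1505, 199, 389, 551, 471, 137 and 295, and with 3-fold and 2-fold they were 62, 250, 6, 14, 23, 31, 1 and 11. Counted at or above the 75th percentile of level, ad libitum higher came to 112, calorie restriction higher to 26 and lower to 33, the opposed counts to 67 and 73, and both higher and both lower to 7 and 34. With the mean of all probe sets, ad libitum higher was 152, calorie restriction lower 46, the opposed counts 65 and 75, and both higher and both lower 7 and 44. Both higher was 19 without a level filter and 19 after repeated quantile normalisation; the cause was not tested. The other 64 counts and correlations under alternatives, including all under cyclic loess, stayed within 1.5 times or with the test's call.

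The limma count for the difference between animals ranged from 0 to 474 when each sample was left out in turn, and the 474 came without the ad libitum animal's sample 1, when the lone sample 2 is assumed to vary like the calorie restriction samples. With the sample number as a replicate block the count was 0; the number pairs no animals and is only shared.

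Under the alternatives fixed beforehand, lists beyond the random range gave 155 medians, of which 136 stayed beyond it on the same side, 17 came within it with the same sign and 2 changed sign. Lists within the range gave 208, of which 192 stayed within, 16 passed it and 24 changed sign. The hormone receptor and inhibin list went from 0.39 to -0.044 with the mean of all probe sets, and the granulosa markers from 0.43 to -0.32 with only members past the level filter; the cause was not tested. Without the ad libitum animal's sample 2, 4 lists that lay beyond the random range between animals no longer did and 12 others passed it. Among named-gene values, 258 stayed and 58 moved, and 3 changed sign, none of them from a change of 2-fold or more (at most 0.055 in size). Signal over background was not analysed here, and 2 of the 12 named genes lower in the ad libitum animal, NOG and CPO, had sample 2 values under the 25th percentile of all genes, as had 1 of the 12 lower in the calorie restriction animal, GAL, and 1 sample each of GAP43, TGFA and WIF1, so the size and rank of these are least sure.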

Other observations

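The test of the hedgehog genes below was set before its other members' values were seen; the genes that prompted it were chosen after. In the antioxidant list (26 genes, median -0.10 in the ad libitum animal, within random lists) 5 were 2-fold lower, among them the glutathione synthesis gene GCLC (-2.42), thioredoxin, TXN (-1.97), its reductase TXNRD1 (-1.91) and NQO1 (-1.18), while GSTM3 (2.00) was 2-fold higher. Of 18 clock and glucocorticoid genes, 5 were higher, PER2 (1.78), TEF (1.62), HLF (1.94, below the level filter), NR1D2 (1.23) and BHLHE41 (2.71), though the list's median came within random lists under 2 alternatives. Cholesterol efflux genes had a median of 0.28, above random lists, with PLTP (1.37) higher.

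Cytosolic ribosomal protein genes moved little but as a group. Their median was 0.22 in the ad libitum animal, above random lists, and 0.12 in the calorie restriction animal, within them, and 18 of 22 had a positive change in both. All 22 had a negative difference between the animals, none of them 2-fold, and in 15 the animals' samples did not overlap (median -0.22, and -0.13 without the ad libitum animal's sample 2, within random lists). Red cell markers lay higher in the calorie restriction animal (median 0.34), with HBB at 1.56, or 0.95 without the ad libitum animal's sample 2. Most red cell markers lay below the level filter, and too few passed it for a median of those alone. Between the animals, smooth muscle and pericyte markers had a median of -0.75, with 6 of 14 2-fold lower in the calorie restriction animal, including DES (-1.70) and LMOD1 (-1.61), and 1 higher, RGS5 (1.31). Without the ad libitum animal's sample 2 that median was -0.54, with 2 genes 2-fold lower, LMOD1 at -0.82 and RGS5 at 0.71.

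IHH (2.78), a hedgehog ligand, and the hedgehog targets PTCH1 (2.22) and HHIP (2.34) were all higher in the ad libitum animal's sample 2, and the hypothesis that hedgehog signalling rose there was tested on other pathway genes. The median of 8 further measured members was 0.35, at percentile 97.7 of random lists, and 7 of 8 had a positive change, with GLI1 (1.57), a target, the only one 2-fold higher. The result may reflect a pathway shift, but the list lay close to the bound of the random range, and the same members had a median of 0.18 at percentile 96.7 in the calorie restriction animal, where PTCH1 was -0.94 and HHIP -0.98. A change in the mix of cells that express these genes was not tested.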
